A study of Mus musculus with 15 samples.

How the data were processed

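Bone marrow cells of NOD mice were cultured for 4 days with 1 ng/ml GM-CSF, with or without 1 ng/ml interleukin-4, and stimulated with 10 µg/ml LPS and 50 ng/ml interferon-γ, per the labels' protocols. Biotin-labelled cRNA was made with an ENZO kit and hybridised to Affymetrix mouse arrays, 1 per sample, per the labels. The deposited values are probe set intensity on a linear scale, and the submitters' processing notes name MAS5, whose version is not given in the sources used here. The authors had scaled each array, since the 2% trimmed mean was 150.1 on all 15 arrays. Signals ran from 0.0133 to 17490. Detection calls and probe-level values were not used here, and no genome coordinates are given. Because MAS5 adjusts and scales each array separately, low signals are noisy and a global change in RNA content would not be seen.

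Samples were grouped by title into 6 groups. The source names of the 0 h GM4 samples mention stimulation although their titles say 0 h, and the protocol of GM4 0 h replicate 1 lacks the doses and gradient. Per the labels, 3 biological replicates were made but not all RNA was good enough for an array. Of 12488 probe sets 66 controls were left out, and 12422 were tested without a filter. The platform annotation gave 1 gene symbol for 10833 probe sets, several for 396 and none for 1193, and 10817 of those with 1 symbol matched a reference gene table by Entrez number, which changed 0 symbols. The probe sets with 1 symbol covered 8251 genes.

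Values were analysed as log2(signal + 16) in R 4.3.3 with limma 3.58.1. A linear model with 6 group means was fitted to all 15 arrays, with 9 residual degrees of freedom and a prior of 4.76, and moderated with an intensity trend. The 9 contrasts were GM4 against GM at each time, 6 and 20 h against 0 h in each DC type, and the differences of those responses. Benjamini-Hochberg adjusted p-values under 0.05 were called, per contrast. These choices, the gene lists, the naming rule and all alternatives except a pair were fixed before the data were examined.

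A gene was represented by its probe set with the highest mean. For GM4 against GM and 6 h against 0 h, the 8 largest increases and 8 largest decreases were candidates for naming among genes that passed and whose arrays did not overlap between the 2 groups. By chance, non-overlap arises for 10% of genes with 3 arrays against 3, 20% with 3 against 2 and 33.3% with 2 against 2. For 20 h against 0 h and the differences of responses the 5 largest each way were taken, the latter without the overlap condition. List members were named with their list. Expressed sequences and unnamed transcripts were only counted. No other probe set of a gene named by rank passed the other way, but several, as for Stmn1 and Fos, did not pass.

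There were 28 lists with 528 genes, 431 of them measured, and 27 lists with at least 5 measured genes were tested: 19 pathways and 8 sets of markers of other cell types. All 27 are on the heat map of list medians. Lists were tested two-sided with limma's camera, with a preset correlation of 0.01 and again with an estimated one, adjusted over the 27 lists. Of 112 list calls 25 held with an estimated correlation, all of them in changes from 0 h within a DC type.

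On simulated data with 200 of 12422 probe sets changed, the fit recovered 83% of changes of log2 1 and 99% of log2 2 for GM4 against GM at 0 h, 70% and 96% at 6 h, and 51% and 92% at 20 h. Recovery was 67% and 97% for GM DC at 6 h, 72% and 96% at 20 h, 72% and 99% for GM4 DC at 6 h, and 66% and 92% at 20 h. For the differences of responses it was 34% and 90% at 6 h and 26% and 83% at 20 h. Between 2.72% and 7.46% of calls were false.

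Alternatives were offsets of 1 and 64, quantile normalization, median centring, a filter at the 40th percentile of mean signal, no intensity trend, array weights, a replicate block, an estimated correlation, the mean of all probe sets of a gene, only the 2 groups compared, counting genes, and leaving out each array in turn. An RNA quality covariate (the mean log2 3′/5′ ratio of Gapdh and β-actin) and a fit without 2 doubted arrays, GM 0 h replicate 3 (highest Gapdh ratio) and GM 6 h replicate 1 (highest hybridisation controls), were chosen after seeing the data. Control ratios were compared by exact two-sided permutation of DC type within times.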

Results

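Dendritic cells (DC), which take up antigen and present it to T cells, were grown from the bone marrow of NOD mice, a strain that develops autoimmune diabetes. Cultures received the growth factor GM-CSF alone (GM DC) or GM-CSF with interleukin-4, a cytokine that signals through STAT6 (GM4 DC). The series title calls GM4 DC therapeutic and GM DC not therapeutic. Purified DC were stimulated with bacterial lipopolysaccharide (LPS), a ligand of Tlr4, together with interferon-γ, and total RNA was taken at 0, 6 and 20 h. Gene expression was measured on 15 oligonucleotide arrays, with n of 3 GM arrays at 0 h, 2 at 6 h and 2 at 20 h, and 3 GM4 arrays at 0 h, 3 at 6 h and 2 at 20 h. The labels describe the replicates as biological. The median probe set signal was 40 to 48.4 per array, and between 29.7% and 35.3% of probe sets per array had a signal below 16. The lowest correlation between replicates of a group was 0.966, and the number of arrays limits the precision. Changes are differences of log2(signal + 16), which understates the change of genes with low signal, and ± after a log2 value is limma's standard error. A gene or list that passed had an adjusted p under 0.05, list medians are log2 differences, all list p-values are adjusted, and a list whose count is given without a p for an estimated correlation kept its call under it.

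RNA quality differed between the DC types. The ratio of 3′ to 5′ signal of the Gapdh control probe sets, which rises as RNA is degraded or incompletely copied, was 1.7 ± 0.395 (SD, n = 7) on GM arrays and 1.16 ± 0.156 (SD, n = 8) on GM4 arrays. In an exact two-sided permutation test within times, p was 0.00333, also 0.00333 after adjustment over 3 measures. The β-actin ratio was 1.81 ± 0.302 (SD, n = 7) on GM arrays and 1.26 ± 0.103 (SD, n = 8) on GM4 arrays, with an exact permutation p of 0.000833, the smallest that the 1200 splits can give, and 0.00125 after adjustment. Hybridisation control probe sets averaged 9.51 ± 0.432 (SD, n = 7) on the log2 scale on GM arrays and 8.77 ± 0.186 (SD, n = 8) on GM4 arrays, with the same exact permutation p of 0.000833 and 0.00125 after adjustment. The density gradient for purification also differed, with 16% metrizamide for GM DC and 14.5% for GM4 DC per the labels. Gradient, these control measures and interleukin-4 all followed the DC type.

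**Figure D1:**
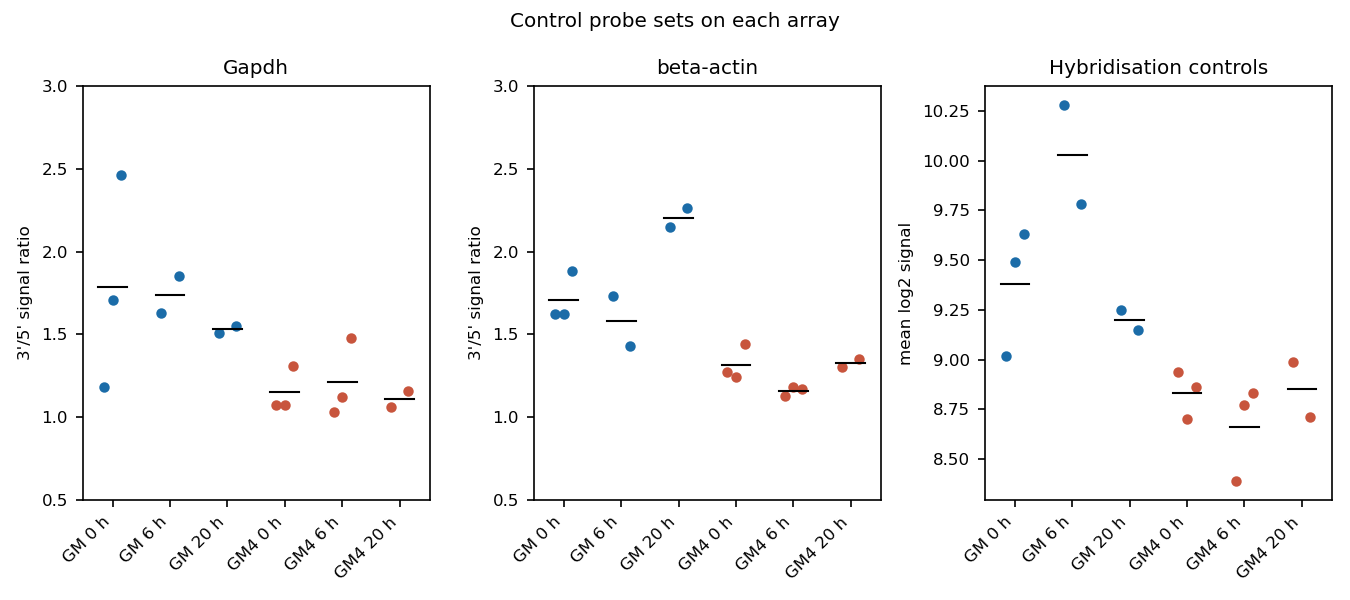
Control measures per array, with the 15 arrays grouped by DC type and time on the horizontal axis and the Gapdh 3′/5′ signal ratio, the β-actin 3′/5′ signal ratio and the mean log2 signal of hybridisation controls on the vertical axes; each point is an array and lines are group means. The Gapdh ratio lay between 1.18 and 2.46 on GM arrays and between 1.03 and 1.48 on GM4 arrays.

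At 0 h, the comparison of GM4 with GM DC asks what growth with interleukin-4 changed. GM4 DC had more transcript of Chil3, a chitinase-like protein induced by interleukin-4, with a signal of 5915 ± 293 (SD, n = 3) against 528.5 ± 82.6 (SD, n = 3) and a log2 difference of 3.46 ± 0.16 (11-fold, adjusted p = 5e-08). Fbp1, an enzyme of gluconeogenesis, was 13.7-fold higher (3.78 ± 0.41). The T cell costimulatory molecules Tnfrsf9 and Cd86 were higher by 2.96 ± 0.27 and 2.91 ± 0.24. Lower in GM4 DC was Mmp8, a neutrophil collagenase (8.4-fold, log2 -3.07 ± 0.50), and the C-type lectin Clec4d differed by -2.75 ± 0.19, with a signal of 97.6 ± 19.2 (SD, n = 3) against 748 ± 106 (SD, n = 3). Cd93 differed by -2.69 ± 0.27, the immediate early gene Fos by -2.50 ± 0.24, the pore-forming protein gene Mpeg1 by -2.38 ± 0.24 and the formyl peptide receptor Fpr2 by -2.09 ± 0.28. Fabp7, a fatty acid-binding protein, was lower by -2.38 ± 0.38 and, at -1.92, did not pass with the RNA quality covariate. In all, 852 of 12422 probe sets were higher and 884 lower, representing 1462 genes, and with each array centred on its median the split was 975 and 630, and with quantile normalization 954 and 798. Without GM 0 h replicate 2 the count of 1736 was 1114, and without GM4 0 h replicate 1 it was 1148. With the RNA quality covariate it was 961, of which 733 were among the 1736, and with only the 2 groups compared 1143.

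Costimulatory and maturation genes were higher as a group in GM4 DC at 0 h. In that list 13 of 14 genes were higher and 1 did not pass (13 higher adjusted over the list alone). The median was 1.65 (adjusted p = 3.79e-16, or p = 0.0795 with an estimated correlation). Members included the lymph node homing receptor Ccr7 (2.25 ± 0.23) and Relb (2.04 ± 0.23), a transcription factor of DC maturation. NF-kappaB pathway genes moved the same way: 11 of 19 genes were higher, 1 was lower and 7 did not pass (12 higher and 2 lower adjusted over the list alone). The median was 0.65 (adjusted p = 2.21e-07, or p = 0.24 with an estimated correlation). Traf1, an adaptor of TNF receptors, was higher by 1.76 ± 0.20 and the adhesion molecule Icam1 by 1.53 ± 0.23. In the interleukin-4 and STAT6 response list 11 of 21 genes were higher, 5 were lower and 5 did not pass (11 higher and 5 lower adjusted over the list alone). The median was 0.83 (adjusted p = 0.0087, or p = 0.0795 with an estimated correlation). The transcription factors Irf4 (2.15 ± 0.25) and Batf3 (2.11 ± 0.18) and the feedback inhibitor Socs2 (1.77 ± 0.18) were among those higher, and Klf4 (-1.55 ± 0.18), Stab1 (-1.50 ± 0.20) and the mannose receptor Mrc1 (-1.22 ± 0.21) among those lower. For MHC class I presentation 3 of 13 genes were higher and 10 did not pass (3 higher adjusted over the list alone). The median was 0.20 (adjusted p = 0.00906, or p = 0.288 with an estimated correlation). The 3 were Psme1 (1.24 ± 0.13), Psmb8 (1.05 ± 0.12) and Psmb9 (0.95 ± 0.12), subunits and a regulator of the immunoproteasome. For plasmacytoid DC markers 2 of 5 genes were higher and 3 did not pass (3 higher adjusted over the list alone). The median was 0.61 (adjusted p = 0.0206, or p = 0.15 with an estimated correlation). Endocytic and phagocytic receptors were lower: 1 of 18 genes was higher, 11 were lower and 6 did not pass (1 higher and 12 lower adjusted over the list alone). The median was -0.89 (adjusted p = 1.39e-06, or p = 0.0795 with an estimated correlation). The lectin Clec4a2 (-1.99 ± 0.20) and the scavenger receptor Msr1 (-1.64 ± 0.17) were lower, whereas Ly75, an antigen uptake receptor of DC, was higher (1.68 ± 0.23). Among monocyte and macrophage markers 7 of 13 genes were lower and 6 did not pass (9 lower adjusted over the list alone). The median was -0.96 (adjusted p = 0.000675, or p = 0.275 with an estimated correlation). They included the LPS co-receptor Cd14 (-2.03 ± 0.17), lysozyme Lyz2 (-1.68 ± 0.17) and the receptor of macrophage growth factor, Csf1r (-1.60 ± 0.20). For the cell cycle 1 of 29 genes was higher, 7 were lower and 21 did not pass (1 higher and 11 lower adjusted over the list alone). The median was -0.50 (adjusted p = 0.00289, or p = 0.556 with an estimated correlation). For cholesterol and fatty acid synthesis 1 of 15 genes was higher, 4 were lower and 10 did not pass (1 higher and 5 lower adjusted over the list alone). The median was -0.43 (adjusted p = 0.0305, or p = 0.288 with an estimated correlation). For stromal and fibroblast markers 4 of 10 genes were lower and 6 did not pass (5 lower adjusted over the list alone). The median was -0.59 (adjusted p = 0.00887, or p = 0.382 with an estimated correlation). On the same arrays the Gapdh 3′/5′ ratio was lower in GM4 DC, and leaving out GM 0 h replicate 3 ended the stromal call (median -0.33), as the RNA quality covariate did for the stromal and plasmacytoid lists (-0.06 and 0.54). The cell cycle call was lost without GM4 0 h replicate 3 (-0.35), the plasmacytoid call without GM 0 h replicate 1 (0.68), and the cholesterol call without GM 0 h replicate 1 (-0.27), GM 0 h replicate 2 (-0.32), GM4 0 h replicate 3 (-0.23) or with an offset of 1 (-0.49).

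The other lists did not pass at 0 h. In the MHC class II list 2 of 16 genes were higher, 5 were lower and 9 did not pass (3 higher and 5 lower adjusted over the list alone). The median was 0.13 (adjusted p = 0.916, or p = 0.958 with an estimated correlation). For neutrophil and granule markers 3 of 16 genes were higher, 3 were lower and 10 did not pass (7 higher and 3 lower adjusted over the list alone). The median was 0.46 (adjusted p = 0.116, or p = 0.624 with an estimated correlation). Lcn2 (1.80 ± 0.30), Ly6g (1.20 ± 0.30) and Ltf (1.01 ± 0.29) were higher, and Mmp8, Fpr2 and Csf3r (-0.81 ± 0.25) lower. For B cell markers 2 of 11 genes were higher and 9 did not pass (2 higher adjusted over the list alone). The median was -0.02 (adjusted p = 0.41, or p = 0.624 with an estimated correlation). For T and NK cell markers 2 of 11 genes were higher, 1 was lower and 8 did not pass (3 higher and 2 lower adjusted over the list alone). The median was 0.00 (adjusted p = 0.702, or p = 0.875 with an estimated correlation). For mast cells, basophils and eosinophils 2 of 13 genes were higher, 1 was lower and 10 did not pass (2 higher and 1 lower adjusted over the list alone). The median was 0.01 (adjusted p = 0.514, or p = 0.624 with an estimated correlation). For erythroid markers 1 of 8 genes was higher, 1 was lower and 6 did not pass (1 higher and 1 lower adjusted over the list alone). The median was -0.27 (adjusted p = 0.916, or p = 0.958 with an estimated correlation). Median, mean and test differed in sign for the cytokine, regulatory, oxidative phosphorylation and B cell lists, none of which passed.

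**Figure D2:**
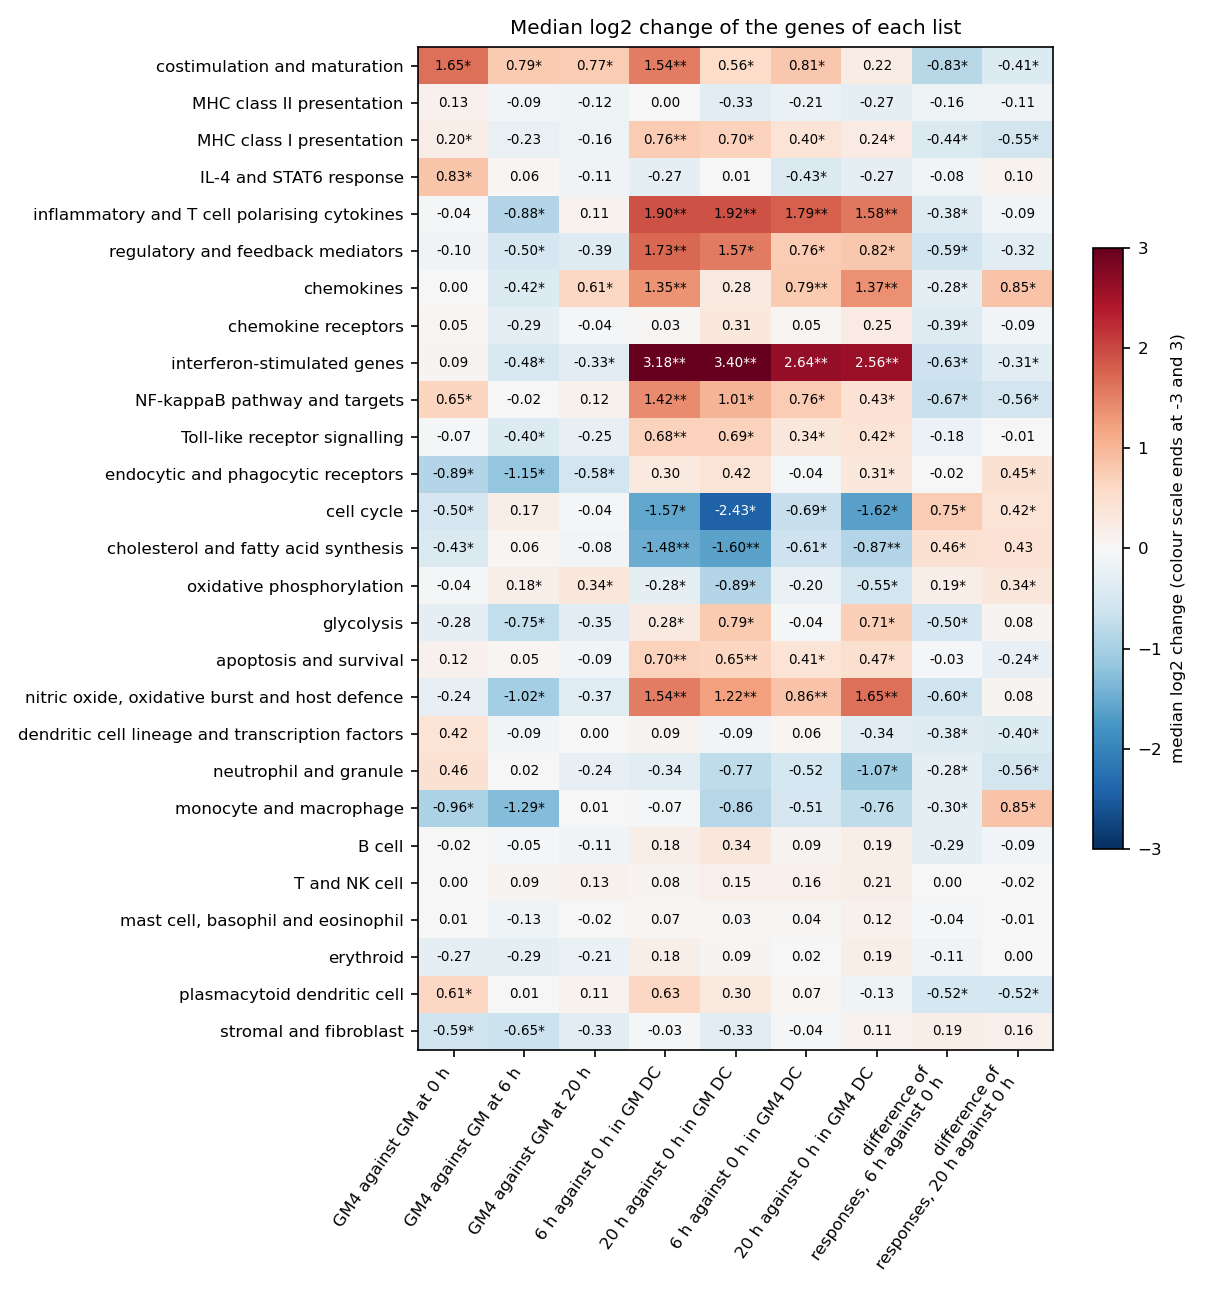
Median log2 difference of each of the 27 gene lists (vertical axis) in each of the 9 comparisons (horizontal axis), as a heat map whose colours end at -3 and 3; 1 star marks a list that passed with the preset correlation and 2 stars one that also passed with an estimated correlation. The costimulation and maturation list had a median of 1.65 for GM4 against GM DC at 0 h and -0.83 for the difference of the 6 h responses.

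At 6 h after stimulation Fst, which encodes the activin-binding protein follistatin, was 9.18-fold lower in GM4 than in GM DC (log2 -3.20 ± 0.26), at 56.57 ± 11.8 (SD, n = 3) against 656.8 ± 185 (SD, n = 2). The soluble pattern recognition molecule Ptx3 differed by -2.90 ± 0.33, the bacterial scavenger receptor Marco by -2.49 ± 0.34, Clec4d by -2.75 ± 0.22 and Lyz2 by -2.68 ± 0.19 (adjusted p = 5.37e-06). Mmp8 differed by -3.05 ± 0.56 and did not pass without GM 6 h replicate 1 (-2.66). Chil3 and Fbp1 were again higher in GM4 DC, by 3.18 ± 0.18 and 4.09 ± 0.46. The protein kinase inhibitor Pkib was higher by 2.48 ± 0.27, the diacylglycerol kinase Dgka by 2.45 ± 0.18, Socs2 by 2.15 ± 0.20 and Tnfrsf9 by 2.21 ± 0.30. In all, 794 probe sets were higher and 589 lower, representing 1175 genes. Without GM 6 h replicate 1 the count of 1383 was 604, and without GM4 6 h replicate 3 it was 881. It was 791 with the RNA quality covariate, of which 601 were among the 1383, 678 without the 2 doubted arrays and 723 with only the 2 groups compared.

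Inflammatory and T cell polarising cytokines were lower in GM4 DC at 6 h: 2 of 14 genes were higher, 7 were lower and 5 did not pass (3 higher and 8 lower adjusted over the list alone). The median was -0.88 (adjusted p = 0.00294, or p = 0.0943 with an estimated correlation). The interleukin-1 genes Il1a (-1.81 ± 0.17) and Il1b (-2.13 ± 0.28) and Il12a (-1.93 ± 0.23), a subunit of the cytokine that drives interferon-producing T cells, were lower. Regulatory and feedback mediators were also lower: 1 of 15 genes was higher, 6 were lower and 8 did not pass (1 higher and 8 lower adjusted over the list alone). The median was -0.50 (adjusted p = 0.000319, or p = 0.181 with an estimated correlation). They included heme oxygenase Hmox1 (-1.70 ± 0.24) and the interleukin-1 antagonist Il1rn (-1.39 ± 0.16). For nitric oxide, oxidative burst and host defence genes 12 of 19 genes were lower and 7 did not pass (2 higher and 16 lower adjusted over the list alone). The median was -1.02 (adjusted p = 3.58e-08, or p = 0.0876 with an estimated correlation). For interferon-stimulated genes 7 of 25 genes were lower and 18 did not pass (12 lower adjusted over the list alone). The median was -0.48 (adjusted p = 8.37e-06, or p = 0.172 with an estimated correlation). For endocytic and phagocytic receptors 12 of 18 genes were lower and 6 did not pass (1 higher and 14 lower adjusted over the list alone). The median was -1.15 (adjusted p = 3.68e-09, or p = 0.0753 with an estimated correlation). In the monocyte and macrophage list 9 of 13 genes were lower and 4 did not pass (9 lower adjusted over the list alone). The median was -1.29 (adjusted p = 2.87e-07, or p = 0.0943 with an estimated correlation). Csf1r (-1.90 ± 0.23) and the Fc receptor Fcgr1 (-1.72 ± 0.26) were lower. For glycolysis 1 of 13 genes was higher, 5 were lower and 7 did not pass (1 higher and 9 lower adjusted over the list alone). The median was -0.75 (adjusted p = 0.000192, or p = 0.261 with an estimated correlation). Smaller shifts were seen for chemokines, where 2 of 18 genes were higher, 6 were lower and 10 did not pass (2 higher and 6 lower adjusted over the list alone). The median was -0.42 (adjusted p = 0.038, or p = 0.283 with an estimated correlation). For Toll-like receptor signalling 1 of 9 genes was higher, 3 were lower and 5 did not pass (1 higher and 3 lower adjusted over the list alone). The median was -0.40 (adjusted p = 0.0397, or p = 0.181 with an estimated correlation). Cxcl14 (-1.41 ± 0.19) and Cd14 (-1.77 ± 0.19) were lower. For stromal and fibroblast markers 1 of 10 genes was lower and 9 did not pass (1 lower adjusted over the list alone). The median was -0.65 (adjusted p = 0.0188, or p = 0.389 with an estimated correlation). The costimulation list was higher in GM4 DC at 6 h: 6 of 14 genes were higher and 8 did not pass (7 higher and 1 lower adjusted over the list alone). The median was 0.79 (adjusted p = 0.000417, or p = 0.283 with an estimated correlation). For oxidative phosphorylation 2 of 35 genes were higher and 33 did not pass (2 higher adjusted over the list alone). The median was 0.18 (adjusted p = 0.0156, or p = 0.494 with an estimated correlation). The Gapdh 3′/5′ ratio was 1.63 and 1.85 on the GM arrays and 1.03, 1.12 and 1.48 on the GM4 arrays at 6 h, and with the RNA quality covariate the calls for chemokines (-0.13), oxidative phosphorylation (0.20) and stromal markers (-0.01) were lost. Without GM 0 h replicate 1, GM 6 h replicate 2 or GM4 6 h replicate 1 the chemokine list (-0.42, -0.22 and -0.32) and the Toll-like receptor list (-0.40, -0.38 and -0.29) did not pass. Nor did they with an offset of 1 (-0.47 and -0.43), or chemokines with quantile normalization (-0.31). Stromal markers did not pass without the latter 2 arrays (-0.33 and -0.59), nor did oxidative phosphorylation without GM 6 h replicate 1 (0.13) or GM4 6 h replicate 3 (0.16). Signs of median, mean and test differed for the DC lineage, cholesterol, plasmacytoid DC and neutrophil lists, which did not pass.

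At 20 h GM4 DC had more Chil3, by 4.13 ± 0.19 (17.6-fold, adjusted p = 6.83e-08). The chemokine Ccl7 was 12.1-fold higher (3.60 ± 0.56), with a signal of 890.6 ± 48.4 (SD, n = 2) against 58.75 ± 0.0687 (SD, n = 2), and Ccl12 was 8.15-fold higher (3.03 ± 0.37). Ccl8 was higher by 2.35 ± 0.38 and did not pass without GM4 20 h replicate 1 (2.13). The vitamin D receptor gene Vdr was higher by 2.82 ± 0.36, Dgka by 2.67 ± 0.20 and the Src family kinase Fyn by 2.66 ± 0.29. Ngp, a neutrophil granule protein, was 8.4-fold lower in GM4 DC (log2 -3.07 ± 0.31), at 22.33 ± 9.09 (SD, n = 2) against 301.9 ± 24.3 (SD, n = 2). The pantetheinase Vnn3 differed by -2.37 ± 0.26, the decoy interleukin-1 receptor Il1r2 by -1.76 ± 0.27 and the chemokine scavenger Ackr3 by -1.66 ± 0.30, the last not passing with an offset of 1 (-1.98) or the RNA quality covariate (-1.05). In all, 390 probe sets were higher and 194 lower, representing 477 genes. The count of 584 was 189 without GM 20 h replicate 2, 146 without GM4 20 h replicate 1 and 269 without GM4 20 h replicate 2. With the RNA quality covariate it was 339, of which 205 were among the 584.

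Chemokines were higher as a group in GM4 DC at 20 h: 8 of 18 genes were higher, 2 were lower and 8 did not pass (9 higher and 2 lower adjusted over the list alone). The median was 0.61 (adjusted p = 0.00014, or p = 0.256 with an estimated correlation). The neutrophil attractant Cxcl5 differed by 2.25 ± 0.37. For costimulation and maturation 6 of 14 genes were higher and 8 did not pass (10 higher adjusted over the list alone). The median was 0.77 (adjusted p = 3.48e-08, or p = 0.256 with an estimated correlation). Tnfsf4, a ligand of activated T cells, differed by 1.92 ± 0.29. For oxidative phosphorylation 5 of 35 genes were higher and 30 did not pass (9 higher adjusted over the list alone). The median was 0.34 (adjusted p = 8.6e-06, or p = 0.359 with an estimated correlation). For interferon-stimulated genes 2 of 25 genes were lower and 23 did not pass (4 lower adjusted over the list alone). The median was -0.33 (adjusted p = 0.000451, or p = 0.359 with an estimated correlation). For endocytic and phagocytic receptors 3 of 18 genes were lower and 15 did not pass (7 lower adjusted over the list alone). The median was -0.58 (adjusted p = 0.000812, or p = 0.358 with an estimated correlation). In the interleukin-4 and STAT6 list, which did not pass, 6 of 21 genes were higher, 2 were lower and 13 did not pass (6 higher and 4 lower adjusted over the list alone). The median was -0.11 (adjusted p = 0.502, or p = 0.729 with an estimated correlation). Of its members, Socs2 (2.33 ± 0.21) and the T cell attractant Ccl17 (2.09 ± 0.26) were higher. The Gapdh 3′/5′ ratio on the 20 h arrays was 1.51 and 1.55 for GM DC and 1.06 and 1.16 for GM4 DC, and without GM 20 h replicate 1 the interferon-stimulated (-0.27) and endocytic (-0.62) calls were lost. Median, mean and test differed in sign for the interleukin-4, DC lineage, monocyte and mast cell lists, which did not pass.

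In GM DC, Cxcl9, a T cell attractant induced by interferon-γ, was 260-fold higher 6 h after stimulation than at 0 h (8.02 ± 0.15, adjusted p = 2e-13). Its signal was 5006 ± 480 (SD, n = 2) against 3.318 ± 1.54 (SD, n = 3). The inflammatory cytokine Il6 rose 114-fold (6.83 ± 0.29) and Il12b, a subunit of cytokines that polarise T cells, 67.9-fold (6.09 ± 0.34). Ptgs2, the inducible prostaglandin synthase, rose by 6.57 ± 0.32, the immunity-related GTPase Iigp1 by 6.18 ± 0.32, the acute-phase gene Saa3 by 5.64 ± 0.47, Cxcl10 by 5.42 ± 0.28 and Ifit2, an antiviral gene, by 5.11 ± 0.23. Falls were in Otulinl (-3.37 ± 0.20), the fatty acid desaturase Scd2 (-3.20 ± 0.26), the transcription factor Lyl1 (-3.04 ± 0.15), ceramide kinase Cerk (-3.02 ± 0.24), the G protein regulator Rgs2 (-2.91 ± 0.20) and the epoxide hydrolase Ephx1 (-2.87 ± 0.21). In all, 1058 probe sets rose and 1954 fell, representing 2512 genes, and with median centring, which moved the median of all probe sets to 0.113, 1584 rose and 1447 fell. Without GM 6 h replicate 1 the count of 3012 was 1929, without the 2 doubted arrays 1958 and with only the 2 groups compared 1943.

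Interferon-stimulated genes rose together in GM DC at 6 h: 24 of 25 genes rose and 1 did not pass (24 up adjusted over the list alone). The median was 3.18 (adjusted p = 9.35e-35). Cytokines rose as well: 11 of 14 genes rose and 3 did not pass (11 up adjusted over the list alone). The median was 1.90 (adjusted p = 1.49e-12). Among them were Il1a (4.89 ± 0.17) and Tnf (4.72 ± 0.32). For chemokines 11 of 18 genes rose, 1 fell and 6 did not pass (11 up and 3 down adjusted over the list alone). The median was 1.35 (adjusted p = 5.56e-08). The neutrophil attractants Cxcl1 (4.39 ± 0.19) and Cxcl2 (4.33 ± 0.27) rose. For costimulation and maturation 12 of 14 genes rose, 1 fell and 1 did not pass (12 up and 1 down adjusted over the list alone). The median was 1.54 (adjusted p = 2.81e-09). Cd40, through which T cells activate DC, rose by 4.62 ± 0.13 and Cd86 by 3.35 ± 0.27. In the NF-kappaB list 17 of 19 genes rose and 2 did not pass (17 up adjusted over the list alone). The median was 1.42 (adjusted p = 8.04e-16). For nitric oxide and host defence genes 12 of 19 genes rose, 1 fell and 6 did not pass (12 up and 1 down adjusted over the list alone). The median was 1.54 (adjusted p = 5.35e-10). The inducible nitric oxide synthase Nos2 rose by 4.94 ± 0.31. For regulatory mediators 10 of 15 genes rose, 2 fell and 3 did not pass (10 up and 3 down adjusted over the list alone). The median was 1.73 (adjusted p = 2.5e-06). Socs3 (4.01 ± 0.36) and Socs1 (3.57 ± 0.22), inhibitors of cytokine signalling, rose. In the MHC class I list 8 of 13 genes rose and 5 did not pass (9 up adjusted over the list alone). The median was 0.76 (adjusted p = 5.6e-07). For Toll-like receptor signalling 4 of 9 genes rose, 1 fell and 4 did not pass (4 up and 1 down adjusted over the list alone). The median was 0.68 (adjusted p = 0.00411). For apoptosis and survival 9 of 18 genes rose, 3 fell and 6 did not pass (9 up and 3 down adjusted over the list alone). The median was 0.70 (adjusted p = 0.0013). Cholesterol and fatty acid synthesis fell: 1 of 15 genes rose, 11 fell and 3 did not pass (1 up and 12 down adjusted over the list alone). The median was -1.48 (adjusted p = 3.12e-05). In the cell cycle 1 of 29 genes rose, 24 fell and 4 did not pass (1 up and 26 down adjusted over the list alone). The median was -1.57 (adjusted p = 5.56e-08, or p = 0.154 with an estimated correlation). Cdc20 (-2.30 ± 0.30) and Rrm2 (-2.06 ± 0.23), needed for mitosis and DNA synthesis, fell. For glycolysis 5 of 13 genes rose and 8 did not pass (5 up adjusted over the list alone). The median was 0.28 (adjusted p = 0.00241, or p = 0.249 with an estimated correlation). For oxidative phosphorylation 1 of 35 genes rose, 11 fell and 23 did not pass (1 up and 13 down adjusted over the list alone). The median was -0.28 (adjusted p = 0.016, or p = 0.422 with an estimated correlation). The glycolysis call was lost with quantile normalization (0.07) and the oxidative phosphorylation call without GM 6 h replicate 1 (-0.20) or the 2 doubted arrays (-0.28). Median, mean and test differed in sign for stromal, neutrophil and monocyte markers, which did not pass.

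**Figure D3:**
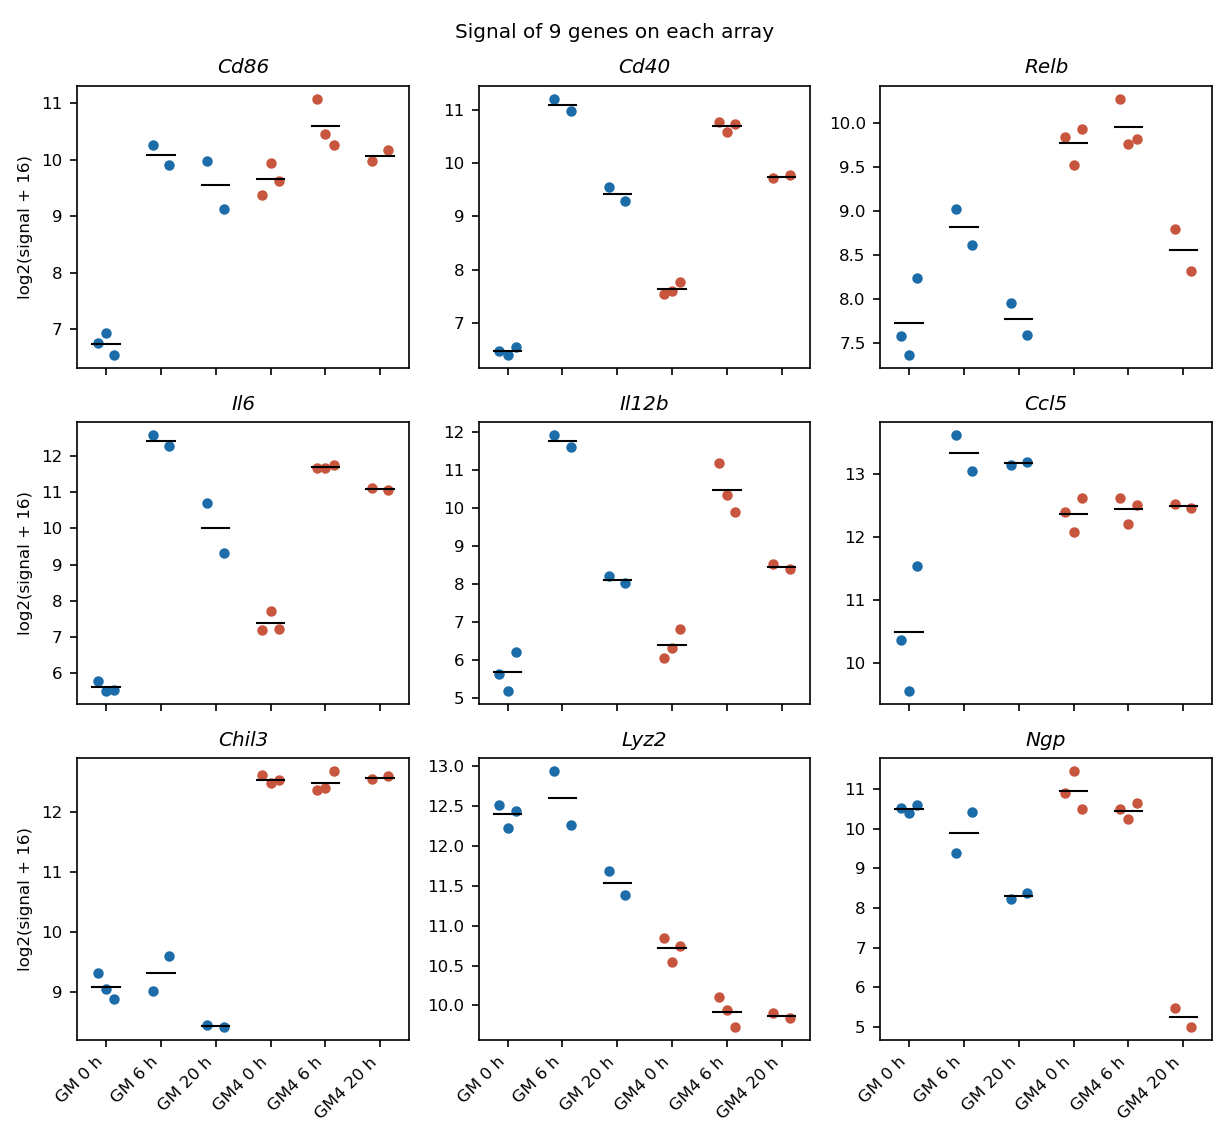
Log2(signal + 16) (vertical axis) of 9 genes on each of the 15 arrays, grouped by DC type and hours after stimulation (horizontal axis); points are arrays and bars are group means. Among the genes shown, Cd40 rose by 4.62 ± 0.13 in GM DC and 3.06 ± 0.11 in GM4 DC at 6 h, and Chil3 was higher in GM4 DC at each time.

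By 20 h GM DC had raised Cxcl9 (6.96 ± 0.15, 124-fold over 0 h) and Ptgs2 (6.25 ± 0.32). Iigp1 was raised by 6.19 ± 0.32, the interferon-induced nucleotide kinase Cmpk2 by 6.18 ± 0.30 and prostaglandin E synthase Ptges by 5.60 ± 0.32, with a signal of 2006 ± 147 (SD, n = 2) against 28.22 ± 17 (SD, n = 3) at 20 and 0 h. The falls were led by Stmn1, a microtubule regulator of dividing cells (37.9-fold, log2 -5.25 ± 0.38, adjusted p = 2.77e-07), S100a4 (-4.48 ± 0.18), Mrc1 (-4.41 ± 0.24) and the cell division genes Cks1b (-4.23 ± 0.22) and Cdk1 (-4.07 ± 0.32). In all, 1370 probe sets rose and 1988 fell, representing 2737 genes. With median centring, which moved the median of all probe sets to 0.127, 2000 rose and 1670 fell.

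Interferon-stimulated genes were raised in GM DC at 20 h: 24 of 25 genes rose and 1 did not pass (24 up adjusted over the list alone). The median was 3.40 (adjusted p = 2.74e-28). In the cytokine list 9 of 14 genes rose and 5 did not pass (9 up adjusted over the list alone). The median was 1.92 (adjusted p = 9.77e-07). For host defence genes 12 of 19 genes rose and 7 did not pass (13 up adjusted over the list alone). The median was 1.22 (adjusted p = 1.71e-08). For apoptosis and survival genes 10 of 18 genes rose and 8 did not pass (11 up adjusted over the list alone). The median was 0.65 (adjusted p = 3.57e-06). For NF-kappaB 15 of 19 genes rose and 4 did not pass (15 up adjusted over the list alone). The median was 1.01 (adjusted p = 3.01e-08, or p = 0.118 with an estimated correlation). In MHC class I presentation 9 of 13 genes rose and 4 did not pass (9 up adjusted over the list alone). The median was 0.70 (adjusted p = 8.62e-06, or p = 0.0718 with an estimated correlation). For regulatory mediators 10 of 15 genes rose, 3 fell and 2 did not pass (10 up and 3 down adjusted over the list alone). The median was 1.57 (adjusted p = 3e-04, or p = 0.128 with an estimated correlation). In glycolysis 8 of 13 genes rose, 1 fell and 4 did not pass (8 up and 1 down adjusted over the list alone). The median was 0.79 (adjusted p = 0.000805, or p = 0.264 with an estimated correlation). For costimulation and maturation 5 of 14 genes rose, 1 fell and 8 did not pass (5 up and 1 down adjusted over the list alone). The median was 0.56 (adjusted p = 0.00461, or p = 0.334 with an estimated correlation). For Toll-like receptor signalling 5 of 9 genes rose, 1 fell and 3 did not pass (5 up and 1 down adjusted over the list alone). The median was 0.69 (adjusted p = 0.0384, or p = 0.125 with an estimated correlation). Cell cycle genes fell together: 1 of 29 genes rose, 23 fell and 5 did not pass (1 up and 24 down adjusted over the list alone). The median was -2.43 (adjusted p = 4.8e-12, or p = 0.0967 with an estimated correlation). Among them was Mki67 (-3.93 ± 0.31). In oxidative phosphorylation 25 of 35 genes fell and 10 did not pass (27 down adjusted over the list alone). The median was -0.89 (adjusted p = 2.71e-09, or p = 0.0887 with an estimated correlation). In cholesterol and fatty acid synthesis 11 of 15 genes fell and 4 did not pass (11 down adjusted over the list alone). The median was -1.60 (adjusted p = 2.95e-06). Without GM 20 h replicate 1 the costimulation (0.22) and Toll-like receptor (0.77) calls were lost, the latter also without GM 0 h replicate 2 (0.67), with median centring (0.81) or with the mean of a gene's probe sets (0.33). Median, mean and test differed in sign for the interleukin-4 and DC lineage lists, which did not pass.

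In GM4 DC, Cxcl9 was 119-fold higher 6 h after stimulation than at 0 h (6.90 ± 0.13, adjusted p = 3.44e-13), at 2394 ± 86.2 (SD, n = 3) against 4.265 ± 1.79 (SD, n = 3). Ptgs2 rose by 5.36 ± 0.29, Saa3 by 5.05 ± 0.42, Cxcl10 by 4.77 ± 0.25, Ifit2 by 4.60 ± 0.20, Iigp1 by 4.58 ± 0.29, the antiviral gene Rsad2 by 4.47 ± 0.31 and the inflammatory cytokine Tnf by 4.44 ± 0.29. Scd2 fell 12.6-fold (log2 -3.66 ± 0.23), Ephx1 by -3.08 ± 0.18 and the transcription factor Egr2 by -2.70 ± 0.19 on the log2 scale. In all, 725 probe sets rose and 1245 fell, representing 1673 genes, and with median centring 842 rose and 963 fell. Array weights gave 3000 in place of 1970.

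In interferon-stimulated genes of GM4 DC at 6 h 24 of 25 genes rose and 1 did not pass (24 up adjusted over the list alone). The median was 2.64 (adjusted p = 2.02e-40). For cytokines 11 of 14 genes rose and 3 did not pass (11 up adjusted over the list alone). The median was 1.79 (adjusted p = 8.61e-14). Among them were Il6 (4.31 ± 0.26) and Il12b (4.08 ± 0.31). For chemokines 9 of 18 genes rose, 1 fell and 8 did not pass (9 up and 1 down adjusted over the list alone). The median was 0.79 (adjusted p = 2.27e-07). For host defence genes 11 of 19 genes rose, 2 fell and 6 did not pass (14 up and 2 down adjusted over the list alone). The median was 0.86 (adjusted p = 2.33e-08). In the NF-kappaB list 12 of 19 genes rose and 7 did not pass (16 up adjusted over the list alone). The median was 0.76 (adjusted p = 5.39e-12, or p = 0.0597 with an estimated correlation). Costimulation and maturation rose too: 7 of 14 genes rose, 2 fell and 5 did not pass (9 up and 2 down adjusted over the list alone). The median was 0.81 (adjusted p = 0.000212, or p = 0.209 with an estimated correlation). Among them were Cd40 (3.06 ± 0.11) and Cd80 (1.20 ± 0.26). For regulatory mediators 10 of 15 genes rose, 2 fell and 3 did not pass (10 up and 2 down adjusted over the list alone). The median was 0.76 (adjusted p = 3.85e-05, or p = 0.0896 with an estimated correlation). For MHC class I presentation 5 of 13 genes rose and 8 did not pass (6 up adjusted over the list alone). The median was 0.40 (adjusted p = 0.000489, or p = 0.103 with an estimated correlation). For apoptosis and survival 6 of 18 genes rose, 3 fell and 9 did not pass (6 up and 3 down adjusted over the list alone). The median was 0.41 (adjusted p = 0.000695, or p = 0.0597 with an estimated correlation). Il1rn (2.66 ± 0.15), the peptide transporter Tap1 (1.10 ± 0.16) and the survival gene Bcl2l1 (1.55 ± 0.15) rose. In Toll-like receptor signalling 4 of 9 genes rose, 1 fell and 4 did not pass (4 up and 1 down adjusted over the list alone). The median was 0.34 (adjusted p = 0.0247, or p = 0.092 with an estimated correlation). Cholesterol and fatty acid synthesis fell: 8 of 15 genes fell and 7 did not pass (9 down adjusted over the list alone). The median was -0.61 (adjusted p = 0.000262, or p = 0.0597 with an estimated correlation). For the cell cycle 1 of 29 genes rose, 9 fell and 19 did not pass (1 up and 16 down adjusted over the list alone). The median was -0.69 (adjusted p = 0.000119, or p = 0.354 with an estimated correlation). For the interleukin-4 and STAT6 list 1 of 21 genes rose, 8 fell and 12 did not pass (1 up and 8 down adjusted over the list alone). The median was -0.43 (adjusted p = 0.0352, or p = 0.0896 with an estimated correlation). That call was lost without GM4 0 h replicate 1 (-0.23), GM4 6 h replicate 2 (-0.32) or the 2 doubted arrays (-0.43). Median, mean and test differed in sign for the chemokine receptor, glycolysis, endocytic, DC lineage, plasmacytoid DC and stromal lists, which did not pass.

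At 20 h in GM4 DC, Cmpk2 (6.20 ± 0.30), Cxcl9 (6.17 ± 0.15), Ptgs2 (6.17 ± 0.32), Saa3 (5.96 ± 0.47) and Ptges (5.95 ± 0.32) led the rises over 0 h. Ngp fell 52.6-fold (log2 -5.72 ± 0.29, adjusted p = 1.48e-08), with 22.33 ± 9.09 (SD, n = 2) against 2046 ± 686 (SD, n = 3) at 20 and 0 h. Fbp1 fell 20.7-fold (-4.37 ± 0.46), and the epithelial and DC surface protein gene Plet1 (-4.18 ± 0.32) and the monocyte chemokine receptor Ccr2 (-3.94 ± 0.27) fell too. In all, 1082 probe sets rose and 1524 fell, representing 2127 genes, and with median centring 1256 rose and 1317 fell. Without GM4 20 h replicate 2 the count of 2606 was 1392.

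For interferon-stimulated genes of GM4 DC 22 of 25 genes rose and 3 did not pass (24 up adjusted over the list alone) at 20 h. The median was 2.56 (adjusted p = 2.12e-30). In the host defence list 14 of 19 genes rose and 5 did not pass (15 up and 1 down adjusted over the list alone). The median was 1.65 (adjusted p = 1.26e-11). For cytokines 10 of 14 genes rose, 1 fell and 3 did not pass (10 up and 1 down adjusted over the list alone). The median was 1.58 (adjusted p = 3.15e-09). Il1a (5.35 ± 0.17) and Il1b (4.09 ± 0.28) rose. For chemokines 9 of 18 genes rose, 3 fell and 6 did not pass (12 up and 3 down adjusted over the list alone). The median was 1.37 (adjusted p = 1.17e-05). Among them were Cxcl2 (4.87 ± 0.27) and Ccl3 (3.32 ± 0.28). Glycolysis rose: 9 of 13 genes rose and 4 did not pass (10 up adjusted over the list alone). The median was 0.71 (adjusted p = 5.82e-05, or p = 0.167 with an estimated correlation). For regulatory mediators 8 of 15 genes rose, 2 fell and 5 did not pass (10 up and 3 down adjusted over the list alone). The median was 0.82 (adjusted p = 0.000548, or p = 0.158 with an estimated correlation). For apoptosis and survival 6 of 18 genes rose, 1 fell and 11 did not pass (7 up and 1 down adjusted over the list alone). The median was 0.47 (adjusted p = 0.00214, or p = 0.0964 with an estimated correlation). For NF-kappaB 6 of 19 genes rose, 1 fell and 12 did not pass (7 up and 2 down adjusted over the list alone). The median was 0.43 (adjusted p = 0.00191, or p = 0.336 with an estimated correlation). Hmox1 (2.84 ± 0.24), the caspase Casp4 (2.37 ± 0.18) and Nfkbiz (2.78 ± 0.21) rose. In Toll-like receptor signalling 3 of 9 genes rose, 1 fell and 5 did not pass (3 up and 1 down adjusted over the list alone). The median was 0.42 (adjusted p = 0.0185, or p = 0.102 with an estimated correlation). In MHC class I presentation 4 of 13 genes rose and 9 did not pass (4 up adjusted over the list alone). The median was 0.24 (adjusted p = 0.022, or p = 0.299 with an estimated correlation). Among endocytic receptors 7 of 18 genes rose, 3 fell and 8 did not pass (7 up and 3 down adjusted over the list alone). The median was 0.31 (adjusted p = 0.0398, or p = 0.336 with an estimated correlation). Cd14 (2.40 ± 0.19) and Marco (4.48 ± 0.34) rose and Mrc1 fell (-3.69 ± 0.24). Cell cycle genes fell: 23 of 29 genes fell and 6 did not pass (25 down adjusted over the list alone). The median was -1.62 (adjusted p = 8.37e-13, or p = 0.0964 with an estimated correlation). In cholesterol and fatty acid synthesis 12 of 15 genes fell and 3 did not pass (12 down adjusted over the list alone). The median was -0.87 (adjusted p = 3.43e-06). In oxidative phosphorylation 18 of 35 genes fell and 17 did not pass (22 down adjusted over the list alone). The median was -0.55 (adjusted p = 7.06e-07, or p = 0.143 with an estimated correlation). Neutrophil and granule markers fell: 3 of 16 genes rose, 9 fell and 4 did not pass (3 up and 11 down adjusted over the list alone). The median was -1.07 (adjusted p = 0.000942, or p = 0.299 with an estimated correlation). Without GM4 20 h replicate 1 the calls for MHC class I (0.25), Toll-like receptors (0.24) and endocytic receptors (0.43) were lost. The endocytic call was also lost without GM 6 h replicate 1, GM 6 h replicate 2, GM 20 h replicate 1 or GM 20 h replicate 2 (0.31 each time) or with median centring (0.35), and median, mean and test differed in sign for monocyte, chemokine receptor and erythroid lists, which did not pass.

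The responses of both DC types shared most of their direction. Of 8251 genes, 413 rose in both types at 6 h, where independent lists would share 51.9, and 781 fell in both against 196. At 20 h 540 rose in both against 100 and 924 fell in both against 219, and the types share no arrays. Opposite calls were made for 2 genes at 6 h and 8 at 20 h, and the log2 changes correlated across genes, which are not independent replicates, with Pearson r of 0.808 at 6 h and 0.828 at 20 h. Between GM4 and GM DC, 166 genes differed at all 3 times, with 113 higher each time, 50 lower each time and 3 in mixed directions.

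The difference of the 6 h responses is the log2 change in GM4 DC minus that in GM DC, so that a positive difference can also be a smaller fall. The sterol hydroxylase Ch25h rose less in GM4 DC (difference -2.84 ± 0.46, adjusted p = 0.0099), as did Socs1 (-2.52 ± 0.29). Cd86, higher in GM4 DC at 0 h, differed by -2.40 ± 0.36 and did not pass without the 2 doubted arrays (-2.12). Cd40 (-1.56 ± 0.17) and Il6 (-2.52 ± 0.39, or -2.36 and not past without GM 6 h replicate 1) rose less, as given above. The chemokine Ccl5 differed by -2.78 ± 0.54 and did not pass without GM 6 h replicate 1 (-2.49), GM4 0 h replicate 1 (-2.76), GM4 0 h replicate 3 (-2.65), GM4 6 h replicate 2 (-2.66), GM4 6 h replicate 3 (-2.82) or with quantile normalization (-2.12). Rgs2 (2.30 ± 0.27) and the Ras regulator Rasa3 (1.85 ± 0.26) fell less in GM4 DC. The translation inhibitor Pdcd4 (1.80 ± 0.18) and the lipid phosphatase Lpin1 (2.11 ± 0.35) also had positive differences, Lpin1 not passing without the 2 doubted arrays (2.24). In all, 55 probe sets had a positive difference and 64 a negative one, representing 108 genes, and with median centring these were 42 and 89. The count of 119 was 182 with the RNA quality covariate, 230 with array weights, 213 with the filter, 76 without GM 0 h replicate 2, 54 without GM 6 h replicate 1, 298 without GM 6 h replicate 2, 69 without GM4 6 h replicate 2 and 77 without GM4 6 h replicate 3.

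Most lists that passed had a negative difference at 6 h. In costimulation and maturation 2 of 14 genes had a negative difference and 12 did not pass (7 negative adjusted over the list alone). The median was -0.83 (adjusted p = 4.29e-10, or p = 0.0721 with an estimated correlation). For NF-kappaB 4 of 19 genes had a negative difference and 15 did not pass (10 negative adjusted over the list alone). The median was -0.67 (adjusted p = 4.29e-10, or p = 0.0866 with an estimated correlation). For interferon-stimulated genes 4 of 25 genes had a negative difference and 21 did not pass (1 positive and 11 negative adjusted over the list alone). The median was -0.63 (adjusted p = 4.29e-10, or p = 0.0721 with an estimated correlation). Among them was Gbp2 (-1.66 ± 0.18). In the host defence list 2 of 19 genes had a negative difference and 17 did not pass (1 positive and 9 negative adjusted over the list alone). The median was -0.60 (adjusted p = 1.43e-06, or p = 0.0721 with an estimated correlation). In the cytokine list 3 of 14 genes had a negative difference and 11 did not pass (5 negative adjusted over the list alone). The median was -0.38 (adjusted p = 8.52e-05, or p = 0.0721 with an estimated correlation). In the regulatory list 2 of 15 genes had a negative difference and 13 did not pass (1 positive and 6 negative adjusted over the list alone). The median was -0.59 (adjusted p = 6.57e-05, or p = 0.116 with an estimated correlation). For MHC class I presentation limma called 0 of 13 genes (6 at an unadjusted p under 0.05, 5 negative adjusted over the list alone). The median was -0.44 (adjusted p = 4.25e-05, or p = 0.0866 with an estimated correlation). For glycolysis limma called 0 of 13 genes (3 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median was -0.50 (adjusted p = 0.00129, or p = 0.223 with an estimated correlation). Among DC lineage genes 1 of 17 genes had a negative difference and 16 did not pass (1 positive and 4 negative adjusted over the list alone). The median was -0.38 (adjusted p = 0.0044, or p = 0.221 with an estimated correlation). Among plasmacytoid DC markers limma called 0 of 5 genes (1 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median was -0.52 (adjusted p = 0.0044, or p = 0.0721 with an estimated correlation). For chemokines 2 of 18 genes had a negative difference and 16 did not pass (2 positive and 5 negative adjusted over the list alone). The median was -0.28 (adjusted p = 0.0212, or p = 0.221 with an estimated correlation). For chemokine receptors 1 of 12 genes had a negative difference and 11 did not pass (2 negative adjusted over the list alone). The median was -0.39 (adjusted p = 0.0166, or p = 0.221 with an estimated correlation). For neutrophil markers limma called 0 of 16 genes (2 at an unadjusted p under 0.05, 1 negative adjusted over the list alone). The median was -0.28 (adjusted p = 0.0193, or p = 0.339 with an estimated correlation). For monocyte markers limma called 0 of 13 genes (2 at an unadjusted p under 0.05, 1 negative adjusted over the list alone). The median was -0.30 (adjusted p = 0.0253, or p = 0.306 with an estimated correlation). The cell cycle list, with medians of -1.57 in GM DC and -0.69 in GM4 DC, had a positive difference, where limma called 0 of 29 genes (14 at an unadjusted p under 0.05, 1 negative adjusted over the list alone). The median was 0.75 (adjusted p = 2.95e-05, or p = 0.234 with an estimated correlation). For cholesterol synthesis limma called 0 of 15 genes (5 at an unadjusted p under 0.05, 2 positive adjusted over the list alone). The median was 0.46 (adjusted p = 0.0339, or p = 0.221 with an estimated correlation). For oxidative phosphorylation limma called 0 of 35 genes (3 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median was 0.19 (adjusted p = 0.0231, or p = 0.362 with an estimated correlation). Calls were lost for chemokines without GM 0 h replicate 1 (-0.20), GM 6 h replicate 2 (-0.08) or GM4 6 h replicate 1 (-0.18), for chemokine receptors without GM4 6 h replicate 3 (-0.22) and for glycolysis without GM 6 h replicate 1 (-0.16). Quantile normalization ended the calls for chemokines (-0.21), glycolysis (-0.21) and monocyte markers (-0.37). Without the 2 doubted arrays glycolysis (-0.20), chemokine receptors (0.02), oxidative phosphorylation (0.11) and monocyte markers (0.07) did not pass. Calls were lost for cholesterol synthesis and oxidative phosphorylation without GM 0 h replicate 2 (0.40 and 0.17), GM4 0 h replicate 3 (0.27 and 0.13) or GM4 6 h replicate 3 (0.40 and 0.13), for cholesterol also without GM 6 h replicate 2 (0.25) or with an offset of 1 (0.52) and for oxidative phosphorylation without GM 6 h replicate 1 (0.08). The neutrophil call was lost without GM 0 h replicate 3 (-0.24), GM 6 h replicate 2 (-0.11), GM4 0 h replicate 2 (-0.14) or GM4 6 h replicate 1 (-0.12). The monocyte call was lost without GM 0 h replicate 2 (-0.10), GM 0 h replicate 3 (-0.24), GM 6 h replicate 1 (-0.01), GM4 0 h replicate 1 (-0.22), GM4 0 h replicate 3 (-0.17), GM4 6 h replicate 3 (-0.05) or with the mean of a gene's probe sets (-0.25).

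At 20 h the difference of responses was largest for named genes in Fbp1 (-4.13 ± 0.65) and Ngp (-3.52 ± 0.41, adjusted p = 0.00259), of which Fbp1 had little signal in GM DC at 0 h (13.4 ± 5.06, SD, n = 3, against 433.5 ± 272, SD, n = 3, in GM4 DC). Ngp fell by -2.19 ± 0.29 in GM DC and -5.72 ± 0.29 in GM4 DC. Rgs2 again fell less in GM4 DC (2.19 ± 0.28), and Gbp2, an interferon-induced GTPase, rose less (-1.82 ± 0.19). Fbp1 and Plac8 (-2.88 ± 0.46) did not pass without GM 20 h replicate 2 (-3.76 and -2.88), GM4 20 h replicate 1 (-4.11 and -2.90) or GM4 20 h replicate 2 (-4.15 and -2.86). Fos fell in GM DC (-2.44) and did not pass in GM4 DC (0.20), a difference of 2.64 ± 0.38, and Clec4d rose more in GM4 DC (2.10 ± 0.31). Neither difference passed without GM4 20 h replicate 2 (2.45 and 1.99). In all, 69 probe sets had a positive difference and 88 a negative one, representing 134 genes, and with median centring these were 32 and 79, but with quantile normalization 100 and 92. The count of 157 was 304 with array weights, 68 without GM 0 h replicate 2, 59 without GM 20 h replicate 1, 41 without GM 20 h replicate 2, 77 without GM4 0 h replicate 1, 104 without GM4 6 h replicate 2, 34 without GM4 20 h replicate 1 and 15 without GM4 20 h replicate 2.

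For chemokines at 20 h 5 of 18 genes had a positive difference, 1 had a negative difference and 12 did not pass (10 positive and 2 negative adjusted over the list alone). The median was 0.85 (adjusted p = 9.92e-06, or p = 0.153 with an estimated correlation). For monocyte and macrophage markers 1 of 13 genes had a positive difference and 12 did not pass (2 positive adjusted over the list alone). The median was 0.85 (adjusted p = 0.000762, or p = 0.247 with an estimated correlation). For oxidative phosphorylation limma called 0 of 35 genes (11 at an unadjusted p under 0.05, 5 positive adjusted over the list alone). The median was 0.34 (adjusted p = 0.000204, or p = 0.284 with an estimated correlation). For the cell cycle limma called 0 of 29 genes (6 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median was 0.42 (adjusted p = 0.00643, or p = 0.473 with an estimated correlation). For endocytic receptors 2 of 18 genes had a positive difference and 16 did not pass (3 positive and 1 negative adjusted over the list alone). The median was 0.45 (adjusted p = 0.0165, or p = 0.284 with an estimated correlation). For NF-kappaB 4 of 19 genes had a negative difference and 15 did not pass (9 negative adjusted over the list alone). The median was -0.56 (adjusted p = 1.35e-06, or p = 0.199 with an estimated correlation). For MHC class I 3 of 13 genes had a negative difference and 10 did not pass (5 negative adjusted over the list alone). The median was -0.55 (adjusted p = 7.21e-06, or p = 0.153 with an estimated correlation). For costimulation 3 of 14 genes had a negative difference and 11 did not pass (6 negative adjusted over the list alone). The median was -0.41 (adjusted p = 9.92e-06, or p = 0.199 with an estimated correlation). For interferon-stimulated genes 3 of 25 genes had a negative difference and 22 did not pass (1 positive and 4 negative adjusted over the list alone). The median was -0.31 (adjusted p = 9.92e-06, or p = 0.185 with an estimated correlation). Among neutrophil and granule markers 1 of 16 genes had a positive difference, 1 had a negative difference and 14 did not pass (1 positive and 4 negative adjusted over the list alone). The median was -0.56 (adjusted p = 0.000628, or p = 0.284 with an estimated correlation). In apoptosis and survival 1 of 18 genes had a negative difference and 17 did not pass (4 negative adjusted over the list alone). The median was -0.24 (adjusted p = 0.00793, or p = 0.185 with an estimated correlation). In the DC lineage 1 of 17 genes had a negative difference and 16 did not pass (2 negative adjusted over the list alone). The median was -0.40 (adjusted p = 0.0195, or p = 0.331 with an estimated correlation). Among plasmacytoid DC markers limma called 0 of 5 genes (2 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median was -0.52 (adjusted p = 0.0301, or p = 0.185 with an estimated correlation). Calls were lost for endocytic receptors without GM 0 h replicate 1 (0.33) or GM 20 h replicate 2 (0.36), for the cell cycle without GM4 0 h replicate 3 (0.29), for the DC lineage without GM4 0 h replicate 1 (-0.30), GM4 20 h replicate 2 (-0.27) or with quantile normalization (-0.42), and for plasmacytoid DC without GM 0 h replicate 1 (-0.58), GM 20 h replicate 1 (-0.63) or GM4 20 h replicate 2 (-0.51). Median, mean and test differed in sign for the interleukin-4, cytokine, Toll-like receptor and T and NK cell lists, which did not pass.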

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

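The tests of class II and CD11c genes, of the level already reached at 0 h and of granulocyte genes, and the RNA quality covariate, were chosen only after the result was seen. Differences of responses that passed are given as log2 change in GM4 DC minus that in GM DC. No group had 4 or more arrays, so single arrays were not tested as outliers.

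At 6 h 119 probe sets differed. The named genes were Rgs2 (2.30), Lpin1 (2.11), Dmtn (1.86, or 1.81 without GM 6 h replicate 1, 1.77 without GM4 6 h replicate 2, or 1.80 without the 2 doubted arrays, not passing each time), Rasa3 (1.85), Pdcd4 (1.80), Ch25h (-2.84), Ccl5 (-2.78), Il6 (-2.52), Socs1 (-2.52) and Cd86 (-2.40). Il6 did not pass without the doubted arrays (-2.32). Il6 and Ccl5 lost calls without other arrays, as given above. All 17 lists that passed lost their call with an estimated correlation (adjusted p = 0.0721 to 0.362), and their median differences were -0.83 for costimulation, -0.44 for MHC class I, -0.38 for cytokines, -0.59 for regulatory mediators, -0.28 for chemokines and -0.39 for chemokine receptors. They were -0.63 for interferon-stimulated genes, -0.67 for NF-kappaB, -0.50 for glycolysis, -0.60 for host defence, -0.38 for the DC lineage, -0.28 for neutrophil, -0.30 for monocyte and -0.52 for plasmacytoid DC markers. They were 0.75 for the cell cycle, 0.46 for cholesterol synthesis and 0.19 for oxidative phosphorylation.

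At 20 h 157 probe sets differed. The named genes were Fos (2.64), Cxcl5 (2.36), Rgs2 (2.19), Cd93 (2.10), Clec4d (2.10), Fbp1 (-4.13), Ngp (-3.52), Plac8 (-2.88), Ccl5 (-2.55) and Tnfrsf9 (-2.44). Tnfrsf9 did not pass without GM 20 h replicate 1 (-2.30), GM 20 h replicate 2 (-2.57) or GM4 20 h replicate 2 (-2.20). Fbp1, Plac8, Fos and Clec4d depended on 20 h arrays, as given above. Cxcl5 did not pass without GM 0 h replicate 1 (2.28), GM 20 h replicate 1 (2.28), GM 20 h replicate 2 (2.44), GM4 0 h replicate 1 (2.21), GM4 0 h replicate 2 (2.42), GM4 6 h replicate 2 (2.36), GM4 20 h replicate 2 (1.79), both doubted arrays (2.12) or with an offset of 1 (2.84). Cd93 did not pass without GM 0 h replicate 1 (1.99), GM 0 h replicate 3 (2.02), GM 20 h replicate 1 (1.72), GM4 0 h replicate 1 (1.99), GM4 0 h replicate 2 (1.96), GM4 20 h replicate 1 (2.29), GM4 20 h replicate 2 (1.91), both doubted arrays (2.02) or with an offset of 1 (1.99). Ccl5 did not pass without any 1 array (-2.70 to -2.09) except GM 0 h replicate 3 and GM 6 h replicate 1, nor with quantile normalization (-2.17) or without the trend (-2.55). All 13 lists that passed lost their call with an estimated correlation (adjusted p = 0.153 to 0.473), and their median differences were -0.41 for costimulation, -0.55 for MHC class I, 0.85 for chemokines, -0.31 for interferon-stimulated genes, -0.56 for NF-kappaB and 0.45 for endocytic receptors. They were 0.42 for the cell cycle, 0.34 for oxidative phosphorylation, -0.24 for apoptosis, -0.40 for the DC lineage, -0.56 for neutrophil, 0.85 for monocyte and -0.52 for plasmacytoid DC markers.

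In a fit of that value alone, also used for the other means here, the costimulation list averaged 1.68 ± 0.16 (SE, 95% interval 1.32 to 2.05) higher in GM4 DC at 0 h, a list call lost with an estimated correlation (adjusted p = 0.0795). With the RNA quality covariate it was 1.91 ± 0.23 (1.38 to 2.44), and under the scaling that gave the lower value 1.74 ± 0.16 (1.37 to 2.10), which argues against either as the whole cause. Class II and CD11c genes, which a larger share of cells lacking them in GM cultures would lower there as well, differed by 0.20 ± 0.24 (-0.33 to 0.73), which argues against such cells as the whole cause, but macrophage-like cells that carry them stay open, as monocyte and macrophage markers were higher in GM DC (median -0.96 for GM4 against GM). Interleukin-4 may account for the difference, as a hypothesis, but gradient and hybridisation control signal followed the same groups and cannot be separated from it. For the 1736 probe sets called at 0 h and 1970 at 6 h in GM4 DC, 1 of 10 splits of the 6 arrays gave as many. The highest other gave 0, and 10 splits cannot give a share under 0.05.

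Of the lists that rose less at 6 h in GM4 DC, 3 were weighed. None kept its call under an estimated correlation (adjusted p = 0.0721, 0.0866 and 0.0721 in turn). Mean differences were -0.96 ± 0.24 for costimulation, -0.70 ± 0.18 for NF-kappaB and -0.59 ± 0.14 for interferon-stimulated genes. The RNA quality covariate gave -0.95, -0.70 and -0.60. Its DC type difference was similar at 0 and 6 h, so it could not decide. Costimulation genes were 1.68 higher at 0 h and 0.73 ± 0.18 (0.32 to 1.14) higher at 6 h in GM4 DC, so a higher starting level may account for their smaller rise. NF-kappaB genes were 0.69 ± 0.12 higher at 0 h and differed by -0.01 ± 0.14 (-0.32 to 0.30) at 6 h, which leaves that explanation open. Interferon-stimulated genes differed by 0.11 ± 0.10 at 0 h and -0.49 ± 0.11 (-0.73 to -0.24) at 6 h, which argues against a higher starting level. Without GM 6 h replicate 1 their difference of rises was -0.63, a value that rests on the 1 GM 6 h array left. The direction thus did not depend on replicate 1. Interleukin-4, gradient and control measures stay open.

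Ngp fell more by 20 h in GM4 DC (difference -3.52 ± 0.48, -4.60 to -2.45). The granulocyte genes Camp, Ltf, S100a8 and S100a9 had a mean difference of -0.85 ± 0.39 (-1.74 to 0.04). Ngp was picked for its large difference, so a smaller mean leaves a loss of granulocyte-lineage cells open. The RNA quality covariate gave -3.56, but its DC type difference was similar at 0 and 20 h, so it decided little. Leaving out either GM4 20 h array gave -3.28 or lower, with 1 array left. Interleukin-4, gradient and control measures stay open.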

How the results depend on the processing

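The RNA quality covariate and the fit without GM 0 h replicate 3 and GM 6 h replicate 1 were tests chosen only after the result was seen. Of 624 named-gene results, calls were lost for 21 with an offset of 1, 15 with 64, 18 with quantile normalization, 20 with median centring, 16 without the trend, 10 with array weights, 5 with the replicate block, 76 with the covariate, 61 without the 2 doubted arrays and, of 566, 63 with only the 2 groups compared. None reversed in these. Leaving out each array in turn kept 458 of 624 gene calls and 84 of 112 list calls in all 15 fits, where a group left with 1 array was assumed to vary like the others. The range of probe sets changed was 1114 to 1743 for GM4 against GM at 0 h, 604 to 1464 at 6 h and 146 to 650 at 20 h. It was 1929 to 3024 and 2383 to 3401 for GM DC at 6 and 20 h, 1381 to 2085 and 1392 to 2711 for GM4 DC, and 54 to 298 and 15 to 168 for the differences of responses. Lists passing ranged from 9 to 11, 9 to 12 and 4 to 9 for GM4 against GM, 13 to 14 and 11 to 14 for GM DC, 12 to 14 and 12 to 15 for GM4 DC, and 13 to 19 and 12 to 14 for the differences. With only the 2 groups compared, which leaves fewer samples, GM4 against GM at 0 and 6 h and GM DC at 6 h gave 1143, 723 and 1943 probe sets, not 1736, 1383 and 3012. The covariate gave 961, 791 and 339 for GM4 against GM at the 3 times and 182 for the 6 h difference of responses, and 8 lists at 20 h. Without the 2 doubted arrays 678 changed for GM4 against GM at 6 h and 1958 for GM DC at 6 h. Array weights gave 3000 for GM4 DC at 6 h and 230 and 304 for the differences of responses, and the filter gave 213 for the 6 h difference. The cause was not tested for the covariate, the weights or the filter. The stromal list at 6 h was not called with the covariate (median -0.01), where the sign of its test but not of its median turned, and the cause was not tested. With an estimated correlation 0 lists passed for GM4 against GM at any time and for both differences of responses, where camera's preset called 10, 12, 5, 17 and 13, and 11, 5, 4 and 5 passed for GM DC at 6 and 20 h and GM4 DC at 6 and 20 h. Deviations of same-numbered GM and GM4 arrays correlated at 0.33, 0.06 and 0.22 at 0 h. At 6 h r was 0.28 and 0.18, and at 20 h 0.30 for both, which mirror each other. All were above 0, and over all probe sets each 0 h array correlated best with its own number. Given the 0.06 the numbers were not taken as pairs, but pairing stays possible. The replicate block gave 206 and 260 probe sets for the differences of responses, and with it the Toll-like receptor list for GM4 against GM at 6 h (-0.28) and the endocytic list for GM4 DC at 20 h (0.28) did not pass. Changes are understated for signals below 16, as given above.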

Other observations

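No further hypothesis was tested for the genes given here, which belong to a list fixed beforehand and were picked for description after their values were seen. In the neutrophil and granule list of GM DC 3 of 16 genes rose, 7 fell and 6 did not pass (3 up and 8 down adjusted over the list alone) between 0 and 20 h. The median was -0.77 (adjusted p = 0.125, or p = 0.589 with an estimated correlation). In GM4 DC 3 rose and 9 fell (adjusted p = 0.000942, or p = 0.299 with an estimated correlation). Genes that fell in GM4 DC included Ngp (-5.72 ± 0.29), lactoferrin Ltf (-3.66 ± 0.33), the calprotectin subunits S100a9 (-2.53 ± 0.27) and S100a8 (-2.28 ± 0.22), the antimicrobial peptide gene Camp (-2.14 ± 0.29), myeloperoxidase Mpo (-2.13 ± 0.42) and the serine protease Prtn3 (-1.85 ± 0.32). Those that rose were Fpr2 (3.18 ± 0.31), the siderophore-binding Lcn2 (1.65 ± 0.34) and the gelatinase Mmp9 (1.06 ± 0.28). In GM DC Mmp8 (-2.49 ± 0.56), Ngp (-2.19 ± 0.29), S100a8 (-1.98 ± 0.22), Ltf (-1.86 ± 0.33), Camp (-1.68 ± 0.29), S100a9 (-1.68 ± 0.27) and Prtn3 (-1.38 ± 0.32) fell, and Lcn2 (3.63 ± 0.34), Mmp9 (1.63 ± 0.28) and Fpr2 (1.13 ± 0.31) rose.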
